A study of Homo sapiens with 12 samples.

How the data were processed

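Gene expression was measured by paired-end RNA sequencing of 12 libraries, 3 for each of 4 groups: OCI-AML2 and MOLM-13 cells with vehicle (DMSO) or selinexor for 36 h. Libraries were poly(A)-selected and not strand-specific, per the labels' protocols. Reads were aligned with STAR to hg38 and processed in R 3.6.1 with DESeq2, per the submitters' processing notes; the counting tool and gene annotation are not given in the sources used here. The authors deposited, for each line, a table of whole-number counts per gene symbol and library, with genes of total 0 left out. The deposited normalized tables hold a signal that equals the count divided by 1 size factor per library, set separately for each line (largest relative difference 5.1e-15), and these values were used only for that check. The authors also deposited a table of log2 fold changes and adjusted p-values for MOLM-13, which gives vehicle over selinexor, so its sign was turned here. The line was taken from the initial in the table's name and the treatment from the letter of each column. The columns carry no replicate numbers, so library numbers follow column order and only name a library.

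From the counts, log2 fold changes, standard errors and p-values were computed with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr (minimum count 10, minimum total count 15), robust quasi-likelihood fits and F tests, and Benjamini-Hochberg adjusted p under 0.05. Each line was fitted alone with its 6 libraries and treatment as the only term. The difference between the lines was tested as the interaction of line and treatment over the 12 libraries, on the genes in both tables. Genes removed by the filter held 0.0996% of the counts in OCI-AML2 and 0.109% in MOLM-13. The common biological coefficient of variation was 0.0478 and 0.0366. CPM values are TMM-scaled within a line. The tables were scaled separately per line by the authors, and levels were compared between lines only through the interaction.

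The 28 gene lists were fixed before the data were examined and tested with camera (limma 3.58.1, preset correlation 0.01), where at least 5 members were tested, with Benjamini-Hochberg adjustment over the lists. Camera with a correlation estimated per list, and fry, were run beside it; fry asks whether the genes of a list move on balance one way and compares them with no other genes. Agreement of the lines was measured by the overlap of calls per direction beside the number that independent lists would share, with Fisher's exact test.

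Genes were named by a rule fixed before the data were examined. Per line, it takes the 10 largest rises and 10 largest falls among genes with adjusted p under 0.05, mean CPM of at least 5 and the 3 selinexor libraries on the same side of the 3 vehicle libraries, skipping genes with only an identifier or clone name. It adds XPO1, P2RY2, CDKN1A, MDM2, MYC and FLT3, up to 4 members of each called list and up to 2 of each other list by smallest p, the 5 rises and 5 falls called in both lines with the largest smaller absolute log2 fold change and mean CPM of at least 5 in both, and the 5 largest differences between the lines in each direction with mean CPM of at least 5 over the 12 libraries. Members named in parentheses because 5 or fewer of a list moved in a direction were chosen after their values were seen. Some genes taken by the rule are not reported here.

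Gene positions come from GENCODE 29 on GRCh38, matched by symbol, and the length and GC content of 12389 of 12691 tested symbols (97.6%) were found there. Without strand, reads of overlapping or antisense genes cannot be told apart, and near-identical histone and FAM72 copies can share reads. Trends over length and GC were removed with mgcv 1.9.3. The procedure was tested on simulated counts with 200 changed genes, changed by 1.5-, 2- or 4-fold. Of the genes changed 2-fold it recovered 64 of 66 (97.0%) for OCI-AML2, 61 of 65 (93.8%) for MOLM-13 and 55 of 67 (82.1%) for the difference between the lines, and of those changed 1.5-fold 82.8%, 84.8% and 71.6%. Over all fold sizes, 10, 8 and 7 unchanged genes were called, among 12059, 11797 and 12481 genes in the step. A raised list was called and 0 of the 26 and 27 unchanged lists were. The simulated genes varied independently of each other, so this does not test the preset correlation of camera. In the data 63.1% and 63.6% of tested genes were called in OCI-AML2 and MOLM-13, far more than the 200 simulated changes. The simulation therefore does not test TMM scaling where most genes change.

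The alternatives were DESeq2's size factors, upper quartile scaling, no filter on low counts, DESeq2 1.42.0, limma voom, thinning to the smallest library of the line, a joint fit of 12 libraries, and leaving out each library in turn. Leaving out libraries for the overlap, and all alternatives for the list differences between the lines, were chosen after seeing the data. A replicate block was planned and not run, since the columns carry no replicate numbers. Comparing the replicate libraries by a chi-square over genes gave 1.60 to 5.56 per gene, with OCI-AML2 vehicle library 2 the farthest from its group (4.04 and 5.56), and no library was counted as a duplicate. Floors cover counting error only, and the 95% intervals of list medians are exact sign-test intervals over the genes of a list, which are not independent replicates.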

Results

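Polyadenylated RNA was sequenced from OCI-AML2 and MOLM-13, established human acute myeloid leukaemia cell lines, after 36 h with vehicle (DMSO) or with selinexor, a small molecule that blocks the nuclear export receptor XPO1. Selinexor was given at 200 nM to OCI-AML2 and at 75 nM to MOLM-13, so that the line and the dose cannot be told apart. Each of the 4 groups held 3 libraries, described by the submitters as biologically independent. Total counts ranged from 9506571 to 11769061 in the OCI-AML2 vehicle libraries, from 8650518 to 9774423 in the OCI-AML2 selinexor libraries, from 8160133 to 9444344 in the MOLM-13 vehicle libraries and from 8114892 to 9711704 in the MOLM-13 selinexor libraries. At these depths, 3 counts in a library corresponded to 0.255 to 0.370 CPM (counts scaled to library size), a floor that covers counting error only. The 10 most abundant genes took 5.12 to 5.26% of the counts with vehicle and 6.87 to 7.02% with selinexor in OCI-AML2, and 6.88 to 6.94% against 8.70 to 8.98% in MOLM-13. Spearman correlations across genes between replicate libraries lay between 0.986 and 0.990, and no pair of libraries held the same values. CPM values are given as mean ± SD of 3 libraries, and log2 fold changes (selinexor over vehicle) as estimate ± SE from 3 against 3 libraries.

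The transcript of the drug target rose in both lines. XPO1 (chromosome 2, 61477849 to 61538626, minus strand) went from 443 ± 22.5 to 683 ± 8.76 CPM in OCI-AML2 and from 380.0 ± 13.4 to 601 ± 23.9 CPM in MOLM-13, log2 fold changes of 0.63 ± 0.040 and 0.66 ± 0.035. CDKN1A (chromosome 6, 36676460 to 36687339), which encodes the cyclin-dependent kinase inhibitor p21, rose from 50.6 ± 2.28 to 142 ± 5.39 CPM in OCI-AML2 and from 138 ± 6.16 to 399 ± 10.8 CPM in MOLM-13. MDM2 (chromosome 12, 68808176 to 68850686), the ubiquitin ligase that acts on p53, rose from 125 ± 7.89 to 204 ± 3.64 CPM in OCI-AML2 and from 162 ± 7.33 to 639 ± 30.6 CPM in MOLM-13. P2RY2 (chromosome 11, 73218298 to 73236352), a receptor for extracellular nucleotides, rose from 109 ± 4.51 to 239 ± 6.36 CPM and from 71.4 ± 4.57 to 205 ± 6.31 CPM in the same order, log2 fold changes of 1.14 ± 0.047 and 1.52 ± 0.051. MYC (chromosome 8, 127735434 to 127741434) rose by 0.47 ± 0.038 and 0.55 ± 0.034 on the log2 scale, and FLT3 (chromosome 13, 28003274 to 28100592), a receptor tyrosine kinase of blood progenitors, by 1.05 ± 0.048 and 0.39 ± 0.036. All 6 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment in both lines, and for each the 3 selinexor libraries lay above the 3 vehicle libraries. XPO1 and CDKN1A share 494 and 146 exonic bases with an annotated gene on the opposite strand. MDM2 shares 785 with AC025423.4 and also overlaps CPM, a gene on that strand. These libraries do not keep the strand.

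**Figure D1:**
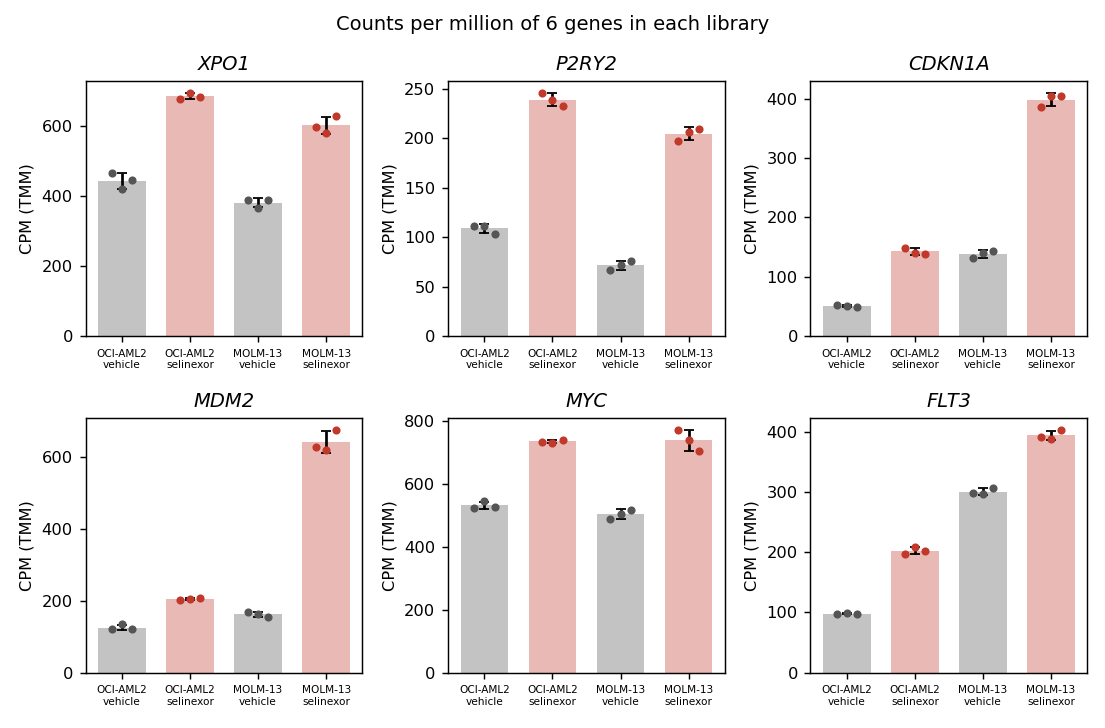
CPM (TMM-scaled, vertical axis) of XPO1, P2RY2, CDKN1A, MDM2, MYC and FLT3 in the vehicle (grey) and selinexor (red) libraries of OCI-AML2 and MOLM-13; bars are means, error bars SD and points the 3 libraries of each group. The selinexor libraries lie above the vehicle libraries for each gene in both lines, and MDM2 shows the larger rise in MOLM-13 (1.98 ± 0.039 against 0.71 ± 0.048 on the log2 scale).

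The comparison within OCI-AML2 asks which transcripts differ after inhibition of XPO1. Genes of cell division, DNA replication and nuclear transport fell, while histone, p53 target, lysosomal and granulocyte genes rose. All 34 tested genes of G2 and mitosis fell (median log2 fold change -1.40, camera adjusted p = 7.3e-57). Among them, CDC20, an activator of the anaphase-promoting complex, changed by -1.46 ± 0.048, and TOP2A, a DNA topoisomerase, by -1.39 ± 0.040. Of 43 genes of S phase and DNA replication, 42 fell (median log2 fold change -0.64, camera adjusted p = 1.3e-17). RRM2, TYMS and CLSPN changed by -1.03 ± 0.041, -1.01 ± 0.044 and -1.27 ± 0.065. RRM2 and TYMS make deoxynucleotides. TYMS shares 967 exonic bases with ENOSF1 on the opposite strand and also overlaps TYMSOS there. Of 27 genes of homologous recombination and the Fanconi pathway, 21 fell and 1 (RMI2) rose (median log2 fold change -0.57, camera adjusted p = 1.2e-04). BRCA1, EXO1, FANCI and RMI2 changed by -0.58 ± 0.058, -0.87 ± 0.062, -0.69 ± 0.050 and 0.88 ± 0.085. Among 31 nuclear transport receptors and Ran cycle genes, 26 fell and 3 (XPO1, KPNA5, NXF1) rose (median log2 fold change -0.55, camera adjusted p = 5.0e-12). The importin genes KPNA2 and KPNB1 fell, as did RCC1, the exchange factor of Ran. KPNA2, KPNB1 and RCC1 changed by -1.77 ± 0.047, -1.05 ± 0.038 and -1.12 ± 0.044.

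By camera with its preset correlation, 5 further lists were called downward in OCI-AML2 and the cytosolic ribosomal proteins upward, and each of these calls was lost with an estimated correlation. Of 33 genes of MYC and ribosome biogenesis, 28 fell and 2 (MYC, CAD) rose (median log2 fold change -0.42, camera adjusted p = 9.4e-08, adjusted p = 0.0618 with an estimated correlation). NCL, NOLC1 and BOP1 changed by -0.68 ± 0.038, -0.70 ± 0.039 and -0.78 ± 0.043. MYC itself is a member of that list, and its transcript rose. Of 44 cytosolic ribosomal protein genes, 41 rose and 1 (RPSA) fell (median log2 fold change 0.41, camera adjusted p = 2.1e-08, adjusted p = 0.277 with an estimated correlation). RPL13, RPS6 and RPS4X changed by 0.61 ± 0.039, 0.57 ± 0.038 and 0.53 ± 0.039. Of 28 genes of the integrated stress response and ATF4 targets, 15 fell and 4 (SLC7A11, PPP1R15A, DDIT4, PSPH) rose (median log2 fold change -0.32, camera adjusted p = 0.0151, adjusted p = 0.115 with an estimated correlation). PSAT1, an enzyme of serine synthesis, fell and SLC7A11, a cystine transporter, rose. PSAT1, ATF4 and SLC7A11 changed by -1.66 ± 0.056, -0.62 ± 0.040 and 1.56 ± 0.049. Of 21 genes of the unfolded protein response, 12 fell and 4 (EDEM1, ERN1, CANX, DNAJB9) rose (median log2 fold change -0.20, camera adjusted p = 0.00317, adjusted p = 0.0779 with an estimated correlation). HSPA5 encodes the main chaperone of the endoplasmic reticulum. HSPA5, HYOU1 and EDEM1 changed by -0.83 ± 0.039, -1.19 ± 0.043 and 0.70 ± 0.051. Of 18 heat shock and chaperone genes, 11 fell and 2 (HSPA4L, HSF1) rose (median log2 fold change -0.26, camera adjusted p = 0.00327, adjusted p = 0.119 with an estimated correlation). HSPD1, HSPA4 and HSP90AB1 changed by -0.64 ± 0.039, -0.59 ± 0.041 and -0.47 ± 0.037. Of 24 genes of cholesterol synthesis and uptake, 17 fell and 1 (SREBF2) rose (median log2 fold change -0.32, camera adjusted p = 4.1e-04, adjusted p = 0.0779 with an estimated correlation). HMGCS1 changed by -0.76 ± 0.056.

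Replication-dependent histone genes had the largest list median in OCI-AML2. All 11 tested members rose (median log2 fold change 2.65, camera adjusted p = 1.1e-08). Members with too few counts were not tested. A member scarce with vehicle could pass that filter through its selinexor libraries alone, which favours rises among the tested members. HIST1H2BK, HIST1H2AC and HIST1H2BN changed by 3.73 ± 0.078, 3.36 ± 0.26 and 3.11 ± 0.27. Reads can be split between near-identical histone copies, so single histone genes are uncertain. Of 35 p53 target genes, 22 rose and 2 (AEN, PMAIP1) fell (median log2 fold change 0.61, camera adjusted p = 4.7e-08). TRIM22, CD82 and PHLDA3 changed by 2.31 ± 0.050, 1.60 ± 0.069 and 1.17 ± 0.068. PMAIP1, which encodes the BH3-only protein NOXA, and AEN, a nuclease, fell. Of 20 FOXO target genes, 14 rose and 2 (SOD2, KLF6) fell (median log2 fold change 0.37, camera adjusted p = 1.1e-04). SESN3, CAT and IRS2 changed by 1.66 ± 0.060, 1.37 ± 0.040 and 0.92 ± 0.050. Of 37 genes of lysosome and autophagy, 23 rose and 3 (ATP6V1B2, ATP6V0D1, FNIP2) fell (median log2 fold change 0.38, camera adjusted p = 9.1e-08). PSAP, GAA and TPP1 changed by 1.65 ± 0.040, 1.53 ± 0.064 and 1.43 ± 0.053, and each encodes a protein of the lysosomal lumen. Of 12 purinergic receptor and nucleotide-handling genes, 6 rose and 4 (ENTPD1, P2RY11, ADORA2B, P2RY6) fell (median log2 fold change 0.31, camera adjusted p = 0.035, adjusted p = 0.119 with an estimated correlation). P2RX1, CD38 and ENTPD1 changed by 1.60 ± 0.075, 1.09 ± 0.054 and -0.62 ± 0.089. Of 25 genes of the type I interferon response, 15 rose and 2 (ISG20, USP18) fell (median log2 fold change 0.59, camera adjusted p = 3.1e-04, adjusted p = 0.0607 with an estimated correlation). BST2 and STAT2 changed by 1.46 ± 0.081 and 1.28 ± 0.078.

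Markers of myeloid cell types moved with selinexor in OCI-AML2. Of 27 monocyte and macrophage markers, 16 rose and 3 (EGR1, FCGR1A, MSR1) fell (median log2 fold change 0.36, camera adjusted p = 2.9e-06). LYZ, TYROBP and TLR2 changed by 2.47 ± 0.042, 1.68 ± 0.047 and 1.24 ± 0.060, and LYZ encodes lysozyme. Of 15 granulocyte markers, 11 rose and 4 (MMP9, PRTN3, FPR2, MPO) fell (median log2 fold change 0.56, camera adjusted p = 6.6e-06). AZU1, CSF3R and CTSG changed by 1.83 ± 0.038, 1.38 ± 0.045 and 0.85 ± 0.041. MPO, myeloperoxidase, and PRTN3, proteinase 3, were among the members that fell. Erythroid and megakaryocyte markers were not called (median log2 fold change 0.13, camera adjusted p = 0.902), although ITGA2B, a platelet integrin, rose by 3.32 ± 0.22 and TFRC, the transferrin receptor, changed by -0.90 ± 0.040; that list's median and mean (0.61) are above 0 and the test points down. Only 4 T, B and NK lymphocyte markers were tested, too few for a set test, and all rose: NCAM1 by 0.67, PAX5 by 1.02, CD79B by 2.14 and NKG7 by 0.45.

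The lists that camera did not call in OCI-AML2 had small medians, apart from HLA class II genes at 0.47. Fry, which compares a list with no other genes, did call some of them. PI3K-AKT-mTOR, BCL2 family, HLA class II and HOXA-MEIS1 genes pointed up (fry adjusted p = 0.029, 7.4e-04, 0.010 and 0.0076). Glycolysis and hypoxia genes pointed down (fry adjusted p = 0.0076). PI3K-AKT-mTOR components (median log2 fold change 0.01, camera adjusted p = 0.737) held PIK3R5 at 1.03 ± 0.058 and IRS2 among 13 rises and 13 falls. Glycolysis and hypoxia genes (median log2 fold change -0.04, camera adjusted p = 0.588) held LDHA at -0.81 ± 0.039 and NDRG1 at 1.02 ± 0.041. Nuclear-encoded oxidative phosphorylation genes (median log2 fold change -0.01, camera adjusted p = 0.52), mitochondrially encoded transcripts (median log2 fold change 0.10, camera adjusted p = 0.747) and NF-kB targets (median log2 fold change -0.15, camera adjusted p = 0.902) were not called. BCL2 family genes (median log2 fold change -0.02, camera adjusted p = 0.241, mean 0.21) and HOXA-MEIS1 and stem or progenitor genes (median log2 fold change -0.01, camera adjusted p = 0.52, mean 0.13) had medians below 0 and tests that point up. BBC3, which encodes PUMA, rose by 1.15 ± 0.087 and BCL2A1 by 1.74 ± 0.11. HLA class II genes (median log2 fold change 0.47, camera adjusted p = 0.373) held HLA-DRB1 at 1.41 ± 0.36.

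Among single genes of OCI-AML2 with mean CPM of at least 5 and groups that did not overlap, NGFR, a nerve growth factor receptor, had no counts in the vehicle libraries and was at least 287-fold higher with selinexor, against a floor of 3 counts over the group. CAPN5, a calpain protease, rose from 0.482 ± 0.519 to 14.02 ± 2.31 CPM. Its log2 fold change of 4.90 became 5.94 without OCI-AML2 vehicle library 1, 4.31 without vehicle library 3 and 5.62 with voom. ARRDC3, an arrestin-domain protein (chromosome 5, 91368724 to 91383359), rose from 3.94 ± 0.568 to 103 ± 5.40 CPM. ALDH2, mitochondrial aldehyde dehydrogenase, rose from 3.85 ± 0.879 to 89.8 ± 1.39 CPM, and TLR8, an endosomal receptor for single-stranded RNA, from 0.933 ± 0.439 to 15.7 ± 2.47 CPM. PCLO, SH3TC1, TRIO, SLC43A2 and HIST1H2BK complete the 10 largest rises, at log2 fold changes of 4.35, 4.19, 3.80, 3.79 and 3.73. The largest falls among such genes were LRRC4 (from 26.9 ± 1.27 to 2.47 ± 0.538 CPM), SPTBN1, a spectrin (from 44.7 ± 5.45 to 8.52 ± 2.04 CPM), and PIK3R3, a regulatory subunit of PI3K (from 14.6 ± 0.495 to 3.0001 ± 0.735 CPM). WDR62, CDKN3, FAM72B, IPCEF1, GPR84, CENPA and PIF1 followed at -2.00, -1.98, -1.84, -1.83, -1.83, -1.82 and -1.82, and FAM72B belongs to a family of near-identical copies, so its value is uncertain. In all, 7625 of 12086 tested genes (63.1%) had an adjusted p under 0.05 by edgeR's quasi-likelihood test, 3785 higher and 3840 lower, of which 874 and 344 changed at least 2-fold. The selinexor and vehicle groups did not overlap for 8017 genes (66.3%), where chance gives 10%. The 18 of 27 lists called by camera became 10 with an estimated correlation. Counts adjusted over the list alone were 6 rises and 5 falls for purinergic receptors and extracellular nucleotide handling, 14 rises and 13 falls for PI3K-AKT-mTOR pathway components, 4 rises and 13 falls for unfolded protein response, 6 rises and 12 falls for nuclear-encoded oxidative phosphorylation, 5 rises and 5 falls for NF-kB targets and inflammatory cytokines, 17 rises and 3 falls for monocyte and macrophage markers and 9 rises and 7 falls for HOXA-MEIS1 and stem or progenitor genes, and equalled those over all genes for the other lists.

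MOLM-13 was compared in the same way. Genes of mitosis, DNA replication and homologous recombination fell, and p53 target and granulocyte genes rose. All 34 tested genes of G2 and mitosis (median log2 fold change -1.84, camera adjusted p = 4.7e-75) and all 43 of S phase and DNA replication fell (median log2 fold change -1.27, camera adjusted p = 2.7e-57). CDK1, the mitotic kinase, changed by -2.08 ± 0.058, MKI67 by -2.02 ± 0.042 and RRM2 by -1.78 ± 0.048; the replicative helicase genes MCM4 and MCM7 changed by -1.39 ± 0.035 and -1.27 ± 0.036. Of 27 genes of homologous recombination and the Fanconi pathway, 23 fell (median log2 fold change -0.998, camera adjusted p = 5.1e-11). BRCA1, CHEK1 and EXO1 changed by -1.39 ± 0.066, -1.52 ± 0.083 and -1.60 ± 0.074. Among 31 nuclear transport genes, 23 fell and 5 (XPO1, KPNA5, XPO6, RANBP2, NXF1) rose (median log2 fold change -0.37, camera adjusted p = 8.0e-09, adjusted p = 0.0548 with an estimated correlation). KPNA2, KPNB1 and RANBP1 changed by -2.05 ± 0.049, -1.13 ± 0.035 and -1.08 ± 0.040. Of 33 p53 target genes, 28 rose and 3 (PMAIP1, SESN2, AEN) fell (median log2 fold change 0.80, camera adjusted p = 1.2e-17). TRIM22, MDM2 and TNFRSF10B changed by 3.43 ± 0.054, 1.98 ± 0.039 and 1.27 ± 0.051, the last encoding a death receptor. Of 10 tested replication-dependent histone genes, 9 rose (median log2 fold change 3.26, camera adjusted p = 1.2e-06, adjusted p = 0.0669 with an estimated correlation). Here too, a member scarce with vehicle could pass the filter through its selinexor libraries alone. HIST1H2AC, HIST1H2BK and HIST1H4I changed by 4.43 ± 0.31, 4.22 ± 0.13 and 4.07 ± 0.21.

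Genes of the integrated stress response fell in MOLM-13 and cytosolic ribosomal protein genes rose, while the calls of the other lists in this group were lost with an estimated correlation. Of 30 genes of the integrated stress response and ATF4 targets, 23 fell and 2 (PPP1R15A, VLDLR) rose (median log2 fold change -0.43, camera adjusted p = 4.5e-10). PHGDH and PSAT1 encode enzymes of serine synthesis. PHGDH, PSAT1 and GARS changed by -1.80 ± 0.046, -1.84 ± 0.044 and -0.91 ± 0.042. Of 33 genes of MYC and ribosome biogenesis, 23 fell and 4 (CAD, MYC, ODC1, MYBBP1A) rose (median log2 fold change -0.28, camera adjusted p = 0.00231, adjusted p = 0.0548 with an estimated correlation). MRTO4, NCL and CAD changed by -0.76 ± 0.049, -0.57 ± 0.030 and 0.74 ± 0.042. Of 44 cytosolic ribosomal protein genes, 41 rose (median log2 fold change 0.41, camera adjusted p = 1.3e-16). RPL23 and RPS4X changed by 0.59 ± 0.029 and 0.56 ± 0.028. Of 21 genes of the unfolded protein response, 13 fell and 3 (ERN1, CANX, EDEM1) rose (median log2 fold change -0.28, camera adjusted p = 0.00904, adjusted p = 0.0696 with an estimated correlation). HSPA5 and SDF2L1 changed by -0.57 ± 0.037 and -1.11 ± 0.078. Of 18 heat shock and chaperone genes, 13 fell and 1 (HSPA4L) rose (median log2 fold change -0.21, camera adjusted p = 0.0245, adjusted p = 0.116 with an estimated correlation). HSPA8 and HSPA4L changed by -0.47 ± 0.029 and 1.02 ± 0.11. Of 24 genes of cholesterol synthesis and uptake, 17 fell and 2 (SREBF2, TM7SF2) rose (median log2 fold change -0.36, camera adjusted p = 0.00175, adjusted p = 0.0777 with an estimated correlation). INSIG1 changed by -0.94 ± 0.076. Of 35 nuclear-encoded oxidative phosphorylation genes, 25 fell and 3 (SDHC, NDUFB5, UQCRC2) rose (median log2 fold change -0.23, camera adjusted p = 0.00455, adjusted p = 0.116 with an estimated correlation). NDUFS7 and CYC1 changed by -0.54 ± 0.049 and -0.46 ± 0.036. Of 13 mitochondrially encoded transcripts, 12 rose (median log2 fold change 0.47, camera adjusted p = 2.2e-07, adjusted p = 0.107 with an estimated correlation). CYTB and ND5 changed by 0.88 ± 0.039 and 0.77 ± 0.038.

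The granulocyte list was called upward in MOLM-13 too, although some of its members moved opposite ways in the lines. Of 11 granulocyte markers, 10 rose and 1 (CTSG) fell (median log2 fold change 0.97, camera adjusted p = 9.4e-09). CSF3R, PRTN3 and CEBPA changed by 1.89 ± 0.078, 1.34 ± 0.030 and 0.97 ± 0.031. CTSG encodes cathepsin G. PRTN3 fell in OCI-AML2 and rose in MOLM-13, while CTSG rose in OCI-AML2 and fell in MOLM-13. Their log2 fold changes, MOLM-13 minus OCI-AML2, differed by 1.51 and -1.45 (edgeR interaction adjusted p = 4.3e-39 and 2.7e-37). Of 20 monocyte and macrophage markers, 9 rose and 2 (FCGR1A, EGR1) fell (median log2 fold change 0.40, camera adjusted p = 6.1e-04, adjusted p = 0.0529 with an estimated correlation). LYZ, TYROBP and FCGR1A changed by 3.04 ± 0.038, 1.28 ± 0.096 and -0.79 ± 0.088. Of 36 genes of lysosome and autophagy, 20 rose and 8 fell (median log2 fold change 0.25, camera adjusted p = 0.027, adjusted p = 0.0839 with an estimated correlation). TPP1 and PSAP changed by 1.18 ± 0.065 and 1.16 ± 0.038. Of 21 FOXO target genes, 13 rose and 4 (SOD2, KLF6, CDKN1B, GADD45B) fell (median log2 fold change 0.62, camera adjusted p = 0.00175, adjusted p = 0.0655 with an estimated correlation). TXNIP and CAT changed by 1.47 ± 0.059 and 0.90 ± 0.039. Of 22 interferon response genes, 8 rose and 3 (CMPK2, USP18, SAMD9L) fell (median log2 fold change 0.24, camera adjusted p = 0.0054, adjusted p = 0.0696 with an estimated correlation). STAT2, BST2 and CMPK2 changed by 1.32 ± 0.075, 1.20 ± 0.054 and -1.53 ± 0.27. Of 12 purinergic genes, 5 (P2RY2, CD38, P2RX1, ADA, P2RX7) rose and 1 (PANX1) fell (median log2 fold change 0.09, camera adjusted p = 0.00166, adjusted p = 0.0565 with an estimated correlation). CD38, P2RX1 and ADA changed by 1.60 ± 0.079, 1.48 ± 0.076 and 1.13 ± 0.095. Erythroid and megakaryocyte markers (4 tested) and T, B and NK lymphocyte markers (3 tested) had too few members for a set test, and NCAM1 fell by 0.25 on the log2 scale.

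Some lists were not called by camera in MOLM-13. PI3K-AKT-mTOR components (median log2 fold change 0.09, camera adjusted p = 0.51), glycolysis and hypoxia genes (median log2 fold change -0.05, camera adjusted p = 0.0599), and BCL2 family genes (median log2 fold change 0.12, camera adjusted p = 0.15) were among them. The others were NF-kB targets (median log2 fold change 0.34, camera adjusted p = 0.208), HLA class II genes (median log2 fold change 0.09, camera adjusted p = 0.534) and HOXA-MEIS1 and stem or progenitor genes (median log2 fold change -0.11, camera adjusted p = 0.476). Fry called each of these lists. PI3K-AKT-mTOR, BCL2 family, NF-kB and HLA class II genes pointed up (fry adjusted p = 0.028, 1.4e-04, 2.1e-04 and 0.0079). Glycolysis and hypoxia genes and HOXA-MEIS1 genes pointed down (fry adjusted p = 1.9e-04 and 0.0036), the latter opposite to OCI-AML2. Without MOLM-13 vehicle library 1 or selinexor library 3, the glycolysis and hypoxia genes were called, at camera adjusted p = 0.0458 and 0.0399. EIF4EBP1, a repressor of translation, changed by -0.86 ± 0.043, LDHA by -0.97 ± 0.032, BBC3 by 1.49 ± 0.10, NFKB2 by 1.01 ± 0.088, HLA-DMA by 1.11 ± 0.16 and MEF2C by -0.78 ± 0.044.

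The largest rises in MOLM-13 by the same limits were ARRDC3 (from 1.74 ± 0.221 to 79.98 ± 6.02 CPM), SLC16A9, a monocarboxylate transporter family member (from 0.684 ± 0.337 to 20.5 ± 1.15 CPM), and HIST1H2AC (from 0.491 ± 0.245 to 10.7 ± 1.60 CPM). HIST1H2BK, HIST1H4I, PNOC, MIR34AHG, TRIM22, MYORG and MALAT1 followed at log2 fold changes of 4.22, 4.07, 3.97, 3.68, 3.43, 3.42 and 3.29. MALAT1, a nuclear long noncoding RNA (chromosome 11, 65497688 to 65506516), rose from 17.2 ± 1.15 to 169 ± 5.76 CPM, and MIR34AHG, the host gene of miR-34a, from 1.38 ± 0.217 to 17.7 ± 2.47 CPM. The largest falls by these limits were CDKN3, a phosphatase of cyclin-dependent kinases (from 35.2 ± 1.74 to 5.28 ± 1.09 CPM), APOBEC3B, a cytidine deaminase (from 12.3 ± 0.9997 to 2.12 ± 0.480 CPM), and DLGAP5 (from 73.2 ± 5.40 to 14.2 ± 0.644 CPM). UBE2C, ERN2, CCNB1, TEDC2, BIRC5, FAM72B and PIMREG followed at -2.33, -2.28, -2.24, -2.21, -2.17, -2.15 and -2.14. ERN2 shares 83 exonic bases with AC012317.1 on the opposite strand and also overlaps PLK1 there. PLK1 is a member of the G2 and mitosis list, and without strand its reads cannot be told apart from those of ERN2 in the overlap. In all, 7506 of 11807 tested genes (63.6%) had an adjusted p under 0.05 by edgeR's quasi-likelihood test, 3751 higher and 3755 lower, of which 858 and 421 changed at least 2-fold. The groups did not overlap for 7739 genes (65.5%), where chance gives 10%. The 20 of 26 lists called by camera became 7 with an estimated correlation. Counts adjusted over the list alone were 12 rises and 8 falls for PI3K-AKT-mTOR pathway components, 14 rises and 4 falls for FOXO target genes, 42 rises for cytosolic ribosomal proteins, 3 rises and 26 falls for nuclear-encoded oxidative phosphorylation, 7 rises and 3 falls for type I interferon response and 10 rises for replication-dependent histones, and equalled those over all genes for the other lists. The authors' deposited table for MOLM-13, with its sign turned to selinexor over vehicle, gave log2 fold changes of 0.65 for XPO1, 1.51 for P2RY2 and 1.97 for MDM2, and 3059 genes higher and 3292 lower.

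**Figure D2:**
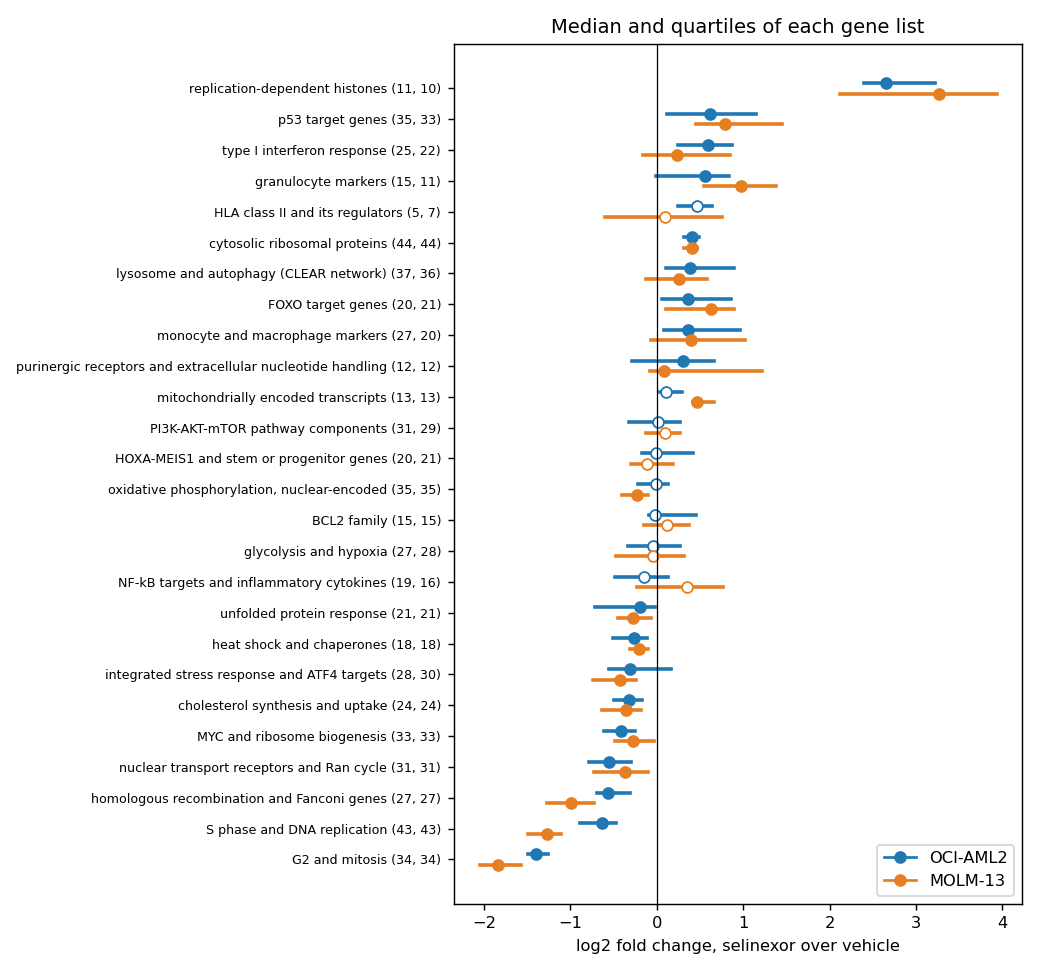
Median log2 fold change, selinexor over vehicle (horizontal axis), of the tested members of 26 gene lists in OCI-AML2 (blue) and MOLM-13 (orange); bars span the quartiles, open circles mark lists whose camera adjusted p was not under 0.05, and numbers in parentheses give the members tested in each line. The replication-dependent histones lie highest (2.65 and 3.26) and the genes of G2 and mitosis lowest (-1.40 and -1.84).

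The responses of the lines were set side by side to ask which genes changed alike. Of 11202 genes tested in both lines, 2356 rose in both, where independent lists would share 1080, and 2649 fell in both, where independent lists would share 1218. The odds ratios were 12.4 and 15.7, and the lines shared no control libraries. A change of at least 2-fold in both lines was found for 363 rises and 170 falls. Among genes with mean CPM of at least 5 in both lines, ranked by the smaller of the 2 changes, ARRDC3, HIST1H2BK, MYORG, HIST1H2AC and HIST1H4I led the shared rises, with log2 fold changes of 4.72, 3.73, 3.72, 3.36 and 3.32 in OCI-AML2 and 5.50, 4.22, 3.42, 4.43 and 4.07 in MOLM-13. CDKN3, WDR62, FAM72B, CENPA and PIF1 led the shared falls by the same ranking, with -1.98, -2.00, -1.84, -1.82 and -1.82 in OCI-AML2 and -2.75, -1.87, -2.15, -2.06 and -2.12 in MOLM-13. A total of 183 genes rose in OCI-AML2 and fell in MOLM-13, and 137 did the opposite. Across genes, which are not independent replicates, the log2 fold changes of the lines had a Pearson r of 0.743 and a Spearman rho of 0.716.

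**Figure D3:**
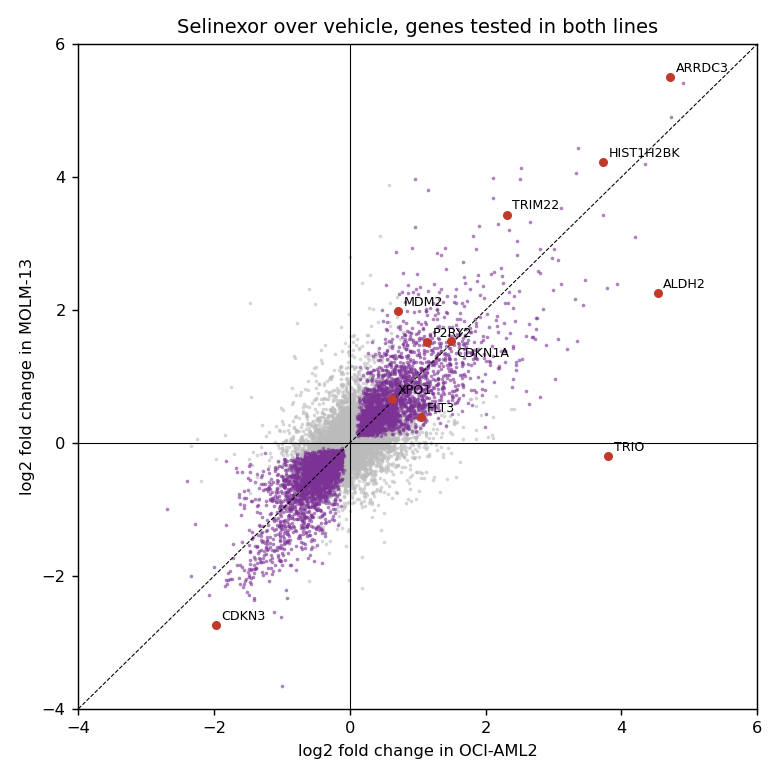
Log2 fold change, selinexor over vehicle, in OCI-AML2 (horizontal axis) and MOLM-13 (vertical axis) for 11202 genes tested in both lines; purple points were called the same way in both, grey points are the others, red points are 11 named genes, the dashed line marks equal change and 1 gene lies outside the axes. ARRDC3 and HIST1H2BK lie at the upper right, CDKN3 at the lower left, and TRIO and ALDH2 to the right of the dashed line.

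Whether the response differed between the lines was tested by the interaction of line and treatment over the 12 libraries. The genes of S phase fell further in MOLM-13, and p53 target genes rose further. Differences are of log2 fold changes, MOLM-13 minus OCI-AML2, and members of a list are counted where that difference passed edgeR's test. MDM2 differed by 1.23 ± 0.063 (edgeR adjusted p = 8.0e-30), P2RY2 by 0.33 ± 0.070 (edgeR adjusted p = 9.2e-05) and FLT3 by -0.71 ± 0.059 (edgeR adjusted p = 1.5e-17). MYC (0.04 ± 0.053, edgeR adjusted p = 0.652), XPO1 (-0.01 ± 0.055, edgeR adjusted p = 0.886) and CDKN1A (-0.01 ± 0.069, edgeR adjusted p = 0.917) were not called, and the sign of the XPO1 and CDKN1A differences turned with DESeq2's size factors, to 0.022 and 0.023. Of 43 genes of S phase and DNA replication, 42 had a lower log2 fold change in MOLM-13 (median difference -0.71, camera adjusted p = 1.3e-40), and of 34 genes of G2 and mitosis 29 did (median difference -0.49, camera adjusted p = 4.4e-14). Of 27 genes of homologous recombination, 18 had a lower log2 fold change in MOLM-13 (median difference -0.52, camera adjusted p = 8.5e-08). Of 35 p53 target genes, 14 had a higher log2 fold change in MOLM-13 and 4 (CD82, SPATA18, DDB2, SESN2) had a lower log2 fold change in MOLM-13 (median difference 0.30, camera adjusted p = 1.2e-05).

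Genes of the integrated stress response (median difference -0.30, camera adjusted p = 9.7e-07), lysosome and autophagy (median difference -0.24, camera adjusted p = 1.5e-04) and nuclear-encoded oxidative phosphorylation (median difference -0.25, camera adjusted p = 6.9e-04, adjusted p = 0.222 with an estimated correlation) had lower log2 fold changes in MOLM-13, at 18 of 30, 17 of 37 and 18 of 35 members. Stress response members called the other way included ATF4 (difference 0.14, edgeR adjusted p = 0.048). The lysosome and autophagy list rose in both lines, by medians of 0.38 in OCI-AML2 and 0.25 in MOLM-13 (adjusted p = 0.0839 with an estimated correlation in MOLM-13), so its negative difference is a smaller median rise. Without STC2, which had a group of libraries at 0, the stress response median was -0.31. Of 33 genes of MYC and ribosome biogenesis, 16 had a higher log2 fold change in MOLM-13 and 2 (NOP16, NOP14) had a lower log2 fold change in MOLM-13 (median difference 0.11, camera adjusted p = 2.2e-04, adjusted p = 0.061 with an estimated correlation). The medians of that list were below 0 in both lines, at -0.42 in OCI-AML2 and -0.28 in MOLM-13. Of 13 mitochondrially encoded transcripts, 6 had a higher log2 fold change in MOLM-13 (median difference 0.27, camera adjusted p = 9.2e-05, adjusted p = 0.234 with an estimated correlation). Of 19 NF-kB targets, 7 had a higher log2 fold change in MOLM-13 and 1 (CCL5) had a lower log2 fold change in MOLM-13 (median difference 0.18, camera adjusted p = 0.0392, adjusted p = 0.0987 with an estimated correlation); without OCI-AML2 vehicle library 1, OCI-AML2 vehicle library 2 or MOLM-13 vehicle library 3 the call ended, at camera adjusted p = 0.0785, 0.0656 and 0.0601. Of 21 HOXA-MEIS1 and stem or progenitor genes, 8 had a lower log2 fold change in MOLM-13 and 1 (CD33) had a higher log2 fold change in MOLM-13 (median difference -0.21, camera adjusted p = 0.0183, adjusted p = 0.138 with an estimated correlation); the call ended without OCI-AML2 vehicle library 2 (camera adjusted p = 0.0656), and the median without IGF2BP2, which had a group at 0, was -0.23. Of 5 T, B and NK lymphocyte markers, 2 (NCAM1, PAX5) had a lower log2 fold change in MOLM-13 (median difference -0.97, camera adjusted p = 0.0183, adjusted p = 0.0889 with an estimated correlation). Among lists not called by camera, the type I interferon response had the largest median difference, at -0.58 over 28 members, and fry called it downward (fry adjusted p = 5.4e-04). PI3K-AKT-mTOR components, also not called, had a median below 0 and a test that points up (median difference -0.05, camera adjusted p = 0.946), and FOXO targets a median below 0, a mean of 0.02 and a test that points down (median difference -0.04, camera adjusted p = 0.927). Counts adjusted over the list alone were 18 higher and 4 lower for p53 target genes, 30 lower for G2 and mitosis, 1 higher and 20 lower for homologous recombination and Fanconi genes, 2 higher and 21 lower for integrated stress response and ATF4 targets, 19 lower for nuclear-encoded oxidative phosphorylation, 7 higher for mitochondrially encoded transcripts and 1 higher and 17 lower for lysosome and autophagy (CLEAR network), and equalled those over all genes for the other called lists.

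The largest single differences among genes with mean CPM of at least 5 over the 12 libraries include PNOC, prepronociceptin, which rose from 4.93 ± 0.699 to 9.58 ± 1.99 CPM in OCI-AML2 and from 0.650 ± 0.364 to 10.6 ± 2.27 CPM in MOLM-13, a difference of 2.96 ± 0.39. ADGRF3, an adhesion receptor, fell from 9.54 ± 1.91 to 6.29 ± 0.961 CPM in OCI-AML2 and rose from 3.24 ± 0.629 to 16.2 ± 1.65 CPM in MOLM-13. It shares 509 exonic bases with SELENOI on the opposite strand. TRIO, a guanine nucleotide exchange factor (chromosome 5, 14143702 to 14532128), rose from 1.04 ± 0.115 to 14.6 ± 0.617 CPM in OCI-AML2 and went from 3.30 ± 0.973 to 2.84 ± 0.974 CPM in MOLM-13, where it was not called. ALDH2 rose in both lines, from 3.85 ± 0.879 to 89.8 ± 1.39 CPM and from 1.29 ± 0.471 to 6.07 ± 1.15 CPM, and CAMK2N2 went from 7.88 ± 0.890 to 8.94 ± 0.731 CPM in OCI-AML2 without a call and fell from 2.64 ± 0.571 to 0.571 ± 0.105 CPM in MOLM-13. CAMK2N2 shares 373 of its 1362 exonic bases with EEF1AKMT4 on the opposite strand. NRSN2, CDKN2A and MGAM had 0 counts in the MOLM-13 vehicle libraries and 8, 6 and 5 in the selinexor libraries together, MANEAL had 6 and 0, and TP73 had 3 and 9 counts in OCI-AML2. These 5 genes were not tested within the line where they are scarce, and their fitted differences depend on the prior count and are no bounds. NRSN2 lost its call without MOLM-13 vehicle library 1, 2 or 3 (fitted difference 4.14, 4.20 and 4.12) or selinexor library 3 (3.30). CDKN2A lost it without OCI-AML2 selinexor library 1, 2 or 3 (4.12, 4.08 and 4.10) or MOLM-13 vehicle library 1, 2 or 3 (4.11, 4.17 and 4.09), and stood at -0.10 without MOLM-13 selinexor library 3 and at 4.72 without selinexor library 2. MGAM lost it with DESeq2 (3.37) and without MOLM-13 vehicle library 1, 2 or 3 (4.10, 4.16 and 4.08) or selinexor library 2 or 3 (3.47 and 3.90). MANEAL lost it without MOLM-13 vehicle library 1 (-3.83), and TP73 without OCI-AML2 vehicle library 3 (-2.04) or selinexor library 2 (-2.12); it stood at -3.34 without vehicle library 2. DESeq2 gave 3.45 for NRSN2, 3.40 for CDKN2A and -4.005 for MANEAL.

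Of 12530 genes tested for the interaction, 3768 (30.1%) were called by edgeR's quasi-likelihood test, 1388 with the MOLM-13 change above and 2380 below the OCI-AML2 change. The share above was 36.8%, and 44.4% with DESeq2's size factors. The split also moved with the libraries included. It was 2023 above and 1542 below without OCI-AML2 vehicle library 1, and 2084 and 1604 without vehicle library 2. Without OCI-AML2 vehicle library 3 it was 2081 and 1646, and without MOLM-13 vehicle library 2 56.8% were above. In these settings, in the same order, the median difference of all tested genes was 0.048, 0.049, 0.050 and 0.052. It was -0.040 in the main fit and -0.0046 with DESeq2's size factors. The split thus goes with a shift of all genes between fits, and no direction is read from it.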

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

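The tests of the dose and of the splits within each line were chosen after the results they bear on were seen. Each result in this part was singled out because the test of the difference between the lines passed its threshold; groups of 3 libraries are too small for a test of single outlying libraries. The response differed between the lines for 3768 genes. Among 100 splits of the 12 libraries, 1, the real split, gave a count as large (highest other 438). These splits remove the treatment effect along with its difference between the lines (0 calls with both lines shuffled, 290 to 438 with 1), so they do not test an equal response, and chance was not excluded by them.

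By gene, the difference in log2 fold change, MOLM-13 minus OCI-AML2, was 1.23 for MDM2, 0.33 for P2RY2, -0.71 for FLT3, 2.96 for PNOC, 2.88 for ADGRF3, -4.05 for TRIO, -2.41 for CAMK2N2 and -2.34 for ALDH2. For NRSN2 (4.12), CDKN2A (4.09), MGAM (4.08), MANEAL (-4.80) and TP73 (-2.66) it rests on few counts in the scarcer line and loses its call when single libraries are left out.

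By list, the median difference was -0.71 for S phase and DNA replication, -0.49 for G2 and mitosis, -0.52 for homologous recombination, 0.30 for p53 targets, 0.11 for MYC and ribosome biogenesis, -0.30 for the integrated stress response, -0.25 for oxidative phosphorylation, 0.27 for mitochondrially encoded transcripts, -0.24 for lysosome and autophagy, 0.18 for NF-kB targets, -0.21 for HOXA-MEIS1 genes and -0.97 for T, B and NK lymphocyte markers. The 12 of 28 lists called by camera became 6 with an estimated correlation. The calls lost were MYC and ribosome biogenesis (adjusted p = 0.061 with an estimated correlation), oxidative phosphorylation (0.222), mitochondrially encoded transcripts (0.234), NF-kB targets (0.0987), HOXA-MEIS1 genes (0.138) and lymphocyte markers (0.0889). NF-kB targets also lost their call without OCI-AML2 vehicle library 1 or 2 or MOLM-13 vehicle library 3 (camera adjusted p = 0.0785, 0.0656 and 0.0601), and HOXA-MEIS1 genes without OCI-AML2 vehicle library 2 (0.0656).

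The larger change of S phase and p53 target genes in MOLM-13 was weighed against technical and general explanations. A uniformly larger response of MOLM-13 would give a slope well above 1 across genes. The slope across 11202 genes was 1.05, and 0.771 by least squares, which argues against such a response. After scaling the OCI-AML2 changes by 1.05, the medians over 43 and 33 members were -0.63 (95% interval -0.72 to -0.54) and 0.32 (0.23 to 0.46). The least squares slope gave -0.79 and 0.52. Both lists were picked for their difference, and a slope near 1 leaves it almost as it was. These intervals therefore add little to the slope itself. For a difference in depth, thinning the 12 libraries to the smallest left -0.70 (from -0.71) and 0.33 (from 0.30). Total counts ranged only from 8114892 to 11769061, so this thinning could move the medians little in any case and decides little about depth. The dose stays open and cannot be told apart from the line, because 0 lines were treated at both doses. A difference in biology between the lines may account for the pattern and was not tested apart from the dose.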

How the results depend on the processing

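The list differences between the lines and the overlap without single libraries were examined under alternatives chosen after seeing the data. No paired analysis was possible because the columns carry no replicate numbers, so the planned replicate block was not run. The counts of changed genes stayed within 1.5 times under all alternatives run: 6533 to 7760 in OCI-AML2, 6351 to 7688 in MOLM-13, and 2924 to 3810 for the difference between the lines. The 3785 rises among 7625 calls of OCI-AML2 (49.6%) became 56.0% with upper quartile scaling, and 49.97% became 57.8% in MOLM-13. The overlap of 5005 fell to 533 when a 2-fold change was also required in both lines, which the added size limit explains. Lists called numbered 10 in OCI-AML2, 7 in MOLM-13 and 6 for the difference between the lines with an estimated correlation, against 18, 20 and 12; the cause was not tested. Fry, which asks another question, called 23, 26 and 21. Each gene taken by the naming rule kept its call and direction within its line where it was tested, in 1344 results without single libraries and 1566 under other alternatives. The rule picks most of these genes for clear changes in the same libraries, so this was largely fixed by that choice. Genes named outside that rule were not followed in this way. Within the lines, leaving out single libraries reversed only the uncalled mitochondrially encoded transcripts of OCI-AML2 (camera adjusted p 0.549 to 0.907), without selinexor library 1. Between the lines, the uncalled differences of XPO1 and CDKN1A changed sign with DESeq2's size factors (0.022, 0.023) and with DESeq2 (0.019, 0.020). Without single libraries they ranged from -0.044 to 0.12 and from -0.047 to 0.11. XPO1 turned without OCI-AML2 vehicle library 1, 2 or 3 (0.041, 0.12, 0.076), MOLM-13 vehicle library 2 or 3 (0.049, 0.0031) or selinexor library 2 (0.013). CDKN1A turned without OCI-AML2 vehicle library 1, 2 or 3 (0.054, 0.068, 0.11), OCI-AML2 selinexor library 1 (0.018), MOLM-13 vehicle library 2 or 3 (0.084, 0.017) or selinexor library 1 (0.0096). CDKN2A ranged from -0.10, without MOLM-13 selinexor library 3, to 4.72. Directions also turned for other uncalled list differences, given as camera adjusted p. PI3K-AKT-mTOR pointed the other way by fry, which tests against no change (fry adjusted p = 0.137), and by camera without OCI-AML2 selinexor library 3 (0.977, range 0.634 to 0.977), and FOXO targets without MOLM-13 vehicle library 2 (0.964, range 0.741 to 0.976). Ribosomal proteins turned without OCI-AML2 vehicle library 1 or 2 (0.526, 0.136), OCI-AML2 selinexor library 3 (0.977) or MOLM-13 vehicle library 2 (0.661), with a range of 0.136 to 0.977. The unfolded protein response turned with DESeq2's size factors (0.921) and without OCI-AML2 vehicle library 1, 2 or 3 (0.662, 0.577, 0.834) or MOLM-13 vehicle library 2 or 3 (0.737, 0.997), with a range of 0.577 to 0.998. Monocyte markers turned without OCI-AML2 selinexor library 3 (0.977) or MOLM-13 selinexor library 3 (0.970), with a range of 0.718 to 0.998. Uncalled differences became called for nuclear transport with DESeq2's size factors (0.0392) and without OCI-AML2 vehicle library 1, 2 or 3 (0.0123, 0.0037, 0.0158) or MOLM-13 vehicle or selinexor library 2 (0.0123, 0.0475). Purinergic genes did so with DESeq2's size factors (0.0487) and without OCI-AML2 vehicle library 1 or 3 (0.0384, 0.0444), OCI-AML2 selinexor library 1 (0.0472) or MOLM-13 selinexor library 1 or 2 (0.0333, 0.0475). Heat shock genes did so without OCI-AML2 vehicle library 1, 2 or 3 (0.0474, 0.0145, 0.0453) or MOLM-13 vehicle library 2 (0.0283). Many of these changes fell in settings where the median difference of all tested genes moved up from -0.040 in the main fit. It stood at 0.048 to 0.052 without OCI-AML2 vehicle library 1, 2 or 3 or MOLM-13 vehicle library 2. With DESeq2's size factors it stood at -0.0046. Whether this shift accounts for each change was not tested. Other splits of the libraries within a line are too few, at 10, for a share under 0.05; the real split called 7625 and 7506 genes and the highest other 0, with 1 split as large in each. For the overlap, 1 of 100 splits of both lines reached 5005 (highest other 0); with no calls in a shuffled line there is none to share, so this adds nothing to the splits within the lines. Depth limits small changes and scarce genes such as NRSN2, CDKN2A and MGAM.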

Other observations

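The lists in this paragraph and the test of 5' TOP mRNAs were chosen after the results were seen. Components of the nuclear pore fell in both lines: of 27 tested, 24 fell and 1 (NUP210) rose in OCI-AML2 and 24 fell and 1 (TPR) rose in MOLM-13, with median log2 fold changes of -0.48 and -0.45 (camera adjusted p = 3.9e-06 and 2.4e-06; 0.0258 and 0.0194 with an estimated correlation). TXNIP and ARRDC4, known targets of the glucose-responsive transcription factor MondoA, had log2 fold changes of 1.47 and 0.88 in MOLM-13. TXNIP is also a member of the FOXO target list. ARRDC3, which encodes another arrestin-domain protein, stood at 5.50. MLXIP, which encodes MondoA, stood at 0.87 and MLX, its partner, at -0.31. In OCI-AML2, ARRDC3 stood at 4.72, TXNIP at 0.84, MLXIP at 0.61 and MLX at -0.41, and ARRDC4 is not given for that line. These genes were picked after their values were seen, so no set test is given for them. Of 12 tested genes of the DREAM complex, a repressor of cell cycle genes, and its partners, 8 fell and 2 (TFDP2, RBL2) rose in OCI-AML2 (median log2 fold change -0.43, camera adjusted p = 0.00726, adjusted p = 0.107 with an estimated correlation), and of 13 in MOLM-13 8 fell and 3 (TFDP2, RBL2, LIN54) rose (median log2 fold change -0.28, camera adjusted p = 0.00144, adjusted p = 0.05001 with an estimated correlation). The lowest were FOXM1 (-1.32 and -1.79) and MYBL2 (-1.17 and -1.88), which encode activators of cell cycle genes, while RBL2, a pocket protein of the repressor, stood at 0.44 and 0.42. Targets of NRF2 were not called in either line (median log2 fold change -0.15, camera adjusted p = 0.94; median log2 fold change -0.15, camera adjusted p = 0.639). Of 6 cholesterol efflux genes and LXR targets in MOLM-13, 3 (SCD, SREBF1, LPCAT3) fell and 2 (MYLIP, ABCA1) rose (median log2 fold change -0.29, camera adjusted p = 0.00437, adjusted p = 0.0524 with an estimated correlation), with SCD at -1.58 and SREBF1 at -1.06, which encode a desaturase and a regulator of lipid synthesis. The list was not called in OCI-AML2 (median log2 fold change -0.14, camera adjusted p = 0.0554), and its difference between the lines was not called either (camera adjusted p = 0.632).

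Replication-dependent histone transcripts, which as a class mostly lack a poly(A) tail, rose in libraries selected for poly(A). The list call was lost in MOLM-13 with an estimated correlation (camera adjusted p = 0.0669). Counts per gene do not show whether the histone reads came from forms with or without a tail. A trend with length and GC content across all genes is argued against as the whole cause. Removing it left medians of 2.55 (from 2.65) in OCI-AML2 and 3.32 (from 3.26) in MOLM-13. The trend was small, with a median absolute shift over all genes of 0.0995 and 0.0791 on the log2 scale. An effect of length or GC particular to histone genes was not tested. More RNA without a tail in the selinexor libraries cannot be told apart from other causes, because only 3 small RNAs of a list of such RNAs were tested in OCI-AML2 (median -0.39, -1.56 to 0.69) and 4 in MOLM-13 (median 0.90, -0.82 to 0.98). MALAT1, a long RNA outside that list whose mature 3' end lacks a tail, rose by 2.18 ± 0.18 and 3.29 ± 0.069, and was picked after its values were seen. A treatment effect on these transcripts themselves may remain and was not tested apart from it.

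Ribosomal protein transcripts rose by list medians of 0.41 and 0.41, a call that was lost in OCI-AML2 with an estimated correlation (adjusted p = 0.277). Removing the trend of length and GC left 0.32 and 0.43, which argues against that trend across all genes as the whole cause. Its median absolute shift over all genes was only 0.0995 and 0.0791, and an effect particular to ribosomal protein genes was not tested. A change shared by mRNAs with a 5' TOP motif is a candidate explanation: such mRNAs outside the ribosome had medians of 0.30 in OCI-AML2 (camera adjusted p = 0.0111, adjusted p = 0.355 with an estimated correlation) and 0.43 in MOLM-13 (camera adjusted p = 3.5e-07, adjusted p = 0.0523 with an estimated correlation). The list was written after the rise was seen, so this stays a hypothesis.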
